A study of Mus musculus with 6 samples.

How the data were processed

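RNA of macrophages derived from bone marrow of 3 mice and cultured with 5TGM1-luc myeloma cells was measured on 6 GeneChip Mouse Gene 2.0 ST arrays, 3 for cultures that had the CSF1R antibody and 3 for cultures that had control IgG, per the labels. Total RNA was taken with an RNeasy kit and labelled with biotin using the WT PLUS reagents, per the labels' protocols. The dose of the IgG is not stated apart from that of the antibody, 0.5 nM.

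The deposited values are probe set intensity values on a linear scale, and RMA and limma are named in the submitters' processing notes, with no version or role. RMA as usually run subtracts background, makes the distribution of values alike on all arrays and sums up probes per probe set, so a shift of most genes in 1 direction would be hidden and fold changes tend to be understated. The level at which probes were summed and the genome build are not given in the sources used here, and no coordinates were used. From the values themselves, all were positive, log2 of each had at most 6 decimals, and medians and quartiles were near equal across arrays. Of the genes, 540 had exactly equal values, with no tolerance, on the 3 antibody arrays and 324 on the 3 IgG arrays, and no 2 arrays were copies of each other, since at most 6.88% of their values were identical.

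Values were taken as log2. Gene names came from the platform annotation, which can be old. Of 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none. Of those with 1 symbol, 99.2% had an Entrez identifier in a RefSeq gene table (GRCm38.p6, used only for names), and 0 symbols changed through it. Probe sets with several symbols or none were not used for genes. Of 22180 genes, 1082 had more than 1 probe set, and the probe set with the highest mean over the 6 arrays was used. No filter on low signal was set. Arrays with no scanner files used here have no measured background, so 1394 olfactory and vomeronasal receptor genes, not thought to be used by macrophages, served as a guide. The 95th percentile of their means was 4.92, and 13116 genes lay above it in at least 1 group, with 6047 of the 6314 called genes among them. This guide was chosen after the data were seen.

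Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with 4 residual degrees of freedom before moderation), with Benjamini-Hochberg adjustment over 22180 genes and a threshold of 0.05. Figures used matplotlib 3.10.9 in Python 3.11.15. The 32 gene lists were written from textbook knowledge before the data were examined, as were the tests and the rule for naming genes. Of 639 listed genes, each counted once over all lists, 568 were measured. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 32 lists, and again with the correlation estimated from the arrays. For each list, members past the gene test were counted over all genes tested and again adjusted over the list alone. Lists share genes, and many are expressed by macrophages and by other cells.

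Genes were named by rule. Csf1r, Csf1 and Il34 were given in any case. The 10 genes with the largest rises and the 10 with the largest falls were taken among those past the test whose groups did not overlap, leaving out predicted genes, small RNAs, olfactory and vomeronasal receptors and immunoglobulin or T cell receptor segments. From each list, up to 4 members with the largest change past the test could be named, or 2 with the smallest p if none passed. A set of 30 genes was picked out after their values were seen, among them Ccn2, C1qa and Ndrg1, which the rule had already named. All of the set, whether or not the text names them, were followed through the alternative settings. Levels are means ± SD over 3 arrays, and SE is limma's moderated standard error of a log2 difference.

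The gene test was tested on simulated data: over 5 runs of 22180 genes with 200 changed, for this comparison of 3 and 3 arrays, 51.2% of genes changed by 0.5 on the log2 scale and 88.2% of those changed by 1 were found, 4.39% of called genes were false, and 0 had the wrong sign. The simulated genes were independent, and far fewer were changed than the 6314 called on the real arrays. These rates therefore need not hold for the real comparison. Alternatives were an intensity trend, robust variances, array weights, arrays centred on their medians, cyclic loess, filters at the 25th and 50th percentile of mean signal, the mean of a gene's probe sets, every probe set, other thresholds, Welch's statistic for counts of genes, other tests of lists, the replicate number as a block and leaving out each array. A filter at the receptor level was added after the data were seen. Differences between medians of lists were tested with 99999 permutations of list membership and 10000 bootstrap resamples of genes. Genes of a list are not independent, so those p-values and intervals describe the genes on these arrays.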

Results

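The data addressed how an antibody against the receptor CSF1R changed gene expression in macrophages grown with myeloma cells. CSF1R is the receptor for the growth factors CSF1 (M-CSF) and IL-34, on which macrophages depend for survival and differentiation. Bone marrow cells of 3 C57BL/KaLwRij mice, the strain in which the 5TGM1 myeloma model arose, were grown with M-CSF for 7 days to give macrophages. These were kept overnight with 5TGM1-luc cells, a murine myeloma line that carries luciferase, and then received 0.5 nM of the CSF1R antibody or a control IgG for 3 days. The cultures were washed 4 times against the myeloma cells before total RNA was taken. Expression was measured on 6 whole-transcript mouse arrays, 3 from antibody-treated and 3 from IgG-treated cultures. The values were intensities, with RMA named in the submitters' processing notes, and were analysed here as log2 for 22180 genes. Median signal over probe sets lay between 4.88 and 4.95 on the 6 arrays. Pearson correlations across all 41345 probe sets were 0.992 to 0.993 between arrays of the same group and 0.984 to 0.985 between arrays of different groups. Nothing in the labels ties a replicate to a mouse, so the p-values measure the spread between these samples, which may be technical. The number of arrays, 3 per group, limits the precision of each value.

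After the CSF1R antibody, 2766 genes were higher and 3548 were lower than with IgG, which was 28.5% of the genes tested. Most changes were small. At least 2-fold changes were seen in 641 of the higher and 14 of the lower genes. The target transcript itself, Csf1r, was higher with the antibody, at 11.72 ± 0.05 (SD, n = 3) against 10.60 ± 0.05, a rise of 1.12 on the log2 scale (SE 0.05; 2.17-fold; limma adjusted p = 2.0e-05). The antibody binds the protein, so this transcript does not check the sample labels. Csf1, the ligand, fell by 0.33 (SE 0.07; adjusted p = 0.017). That call was lost when any of 4 arrays was left out, with adjusted p = 0.053 without antibody replicate 1, 0.060 without antibody replicate 2, 0.064 without IgG replicate 2 and 0.061 without IgG replicate 3. Il34, the other ligand, was at 4.48 ± 0.12 and 4.44 ± 0.07 (adjusted p = 0.70). Both values were below 4.92, the 95th percentile of 1394 olfactory and vomeronasal receptor genes, which served as a guide to background. The 3 values of one group lay wholly above those of the other for 8725 genes, or 39.3%, where chance gives 10%. With cyclic loess scaling of the arrays, 3334 genes were higher and 2444 lower, so the share of called genes that were higher was 57.7% in place of 43.8%.

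The 10 largest rises ran from 2.64 to 4.14 on the log2 scale. Ccl8, a chemokine for monocytes, went from 5.28 ± 0.18 with IgG to 9.42 ± 0.17 with the antibody (SD, n = 3), a rise of 4.14 (SE 0.12; 17.6-fold). Il1b, the inflammatory cytokine IL-1 beta, rose by 3.35 (SE 0.10; 10.2-fold), and Ccl12, another monocyte chemokine, rose by 3.04 (SE 0.08; 8.21-fold). Next came Adgre4, which encodes a macrophage adhesion receptor of the F4/80 family, at 3.00 (SE 0.13), and Clec4e, which encodes the glycolipid receptor Mincle, at 2.74 (SE 0.07). Aoah, whose product inactivates bacterial lipopolysaccharide, rose by 2.68 (SE 0.05), the interferon-induced GTPase gene Gbp5 by 2.67 (SE 0.10) and the growth factor gene Nrg1 by 2.64 (SE 0.10). Apol7c (3.09, SE 0.20) and Ifit1bl1 (2.88, SE 0.10) completed the 10, and both lay below the background guide with IgG, so their fold changes are less certain. Adjusted p for these 10 genes ran from 8.1e-06 to 8.8e-05.

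The 10 largest falls were smaller, from 1.03 to 1.29 on the log2 scale. Acta2, which encodes smooth muscle actin, fell by 1.20 (SE 0.05), from 10.31 ± 0.04 to 9.11 ± 0.04 (SD, n = 3; adjusted p = 1.5e-05). Cnn1, the gene of the actin-binding protein calponin, fell by 1.20 (SE 0.15), Postn, which encodes the matrix protein periostin, by 1.08 (SE 0.04) and Ccn2, a matrix-associated growth factor gene, by 1.09 (SE 0.08). Fabp7, for a fatty acid binding protein, fell by 1.26 (SE 0.05) and Pdk4, an inhibitor of pyruvate dehydrogenase, by 1.08 (SE 0.09). Ankrd1 fell by 1.09 (SE 0.15), Zfp640 by 1.13 (SE 0.12) and Dmpk by 1.03 (SE 0.08). Vsig4, a complement receptor gene of tissue macrophages, fell by 1.29 (SE 0.19), but its means of 4.93 and 3.63 lay at and below the background guide. Genes left out of this ranking (predicted genes, small RNAs, odorant and pheromone receptors, immunoglobulin segments) made up 153 of the higher and 281 of the lower genes.

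**Figure D1:**
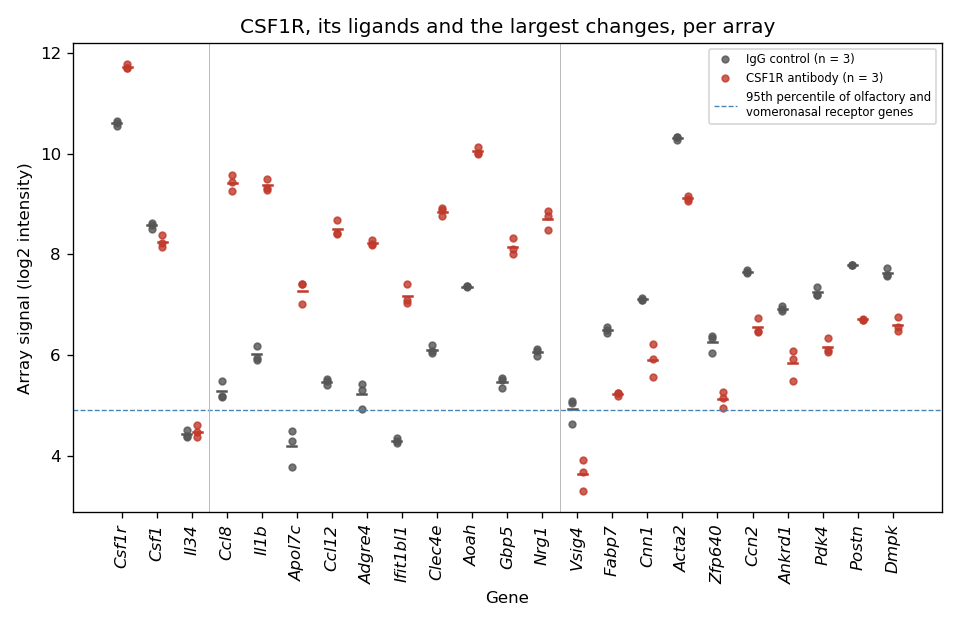
Array signal (log2 intensity) of Csf1r, its ligands and the 10 largest rises and falls, with 1 point per array and a bar at the mean of 3 (grey, IgG; red, CSF1R antibody). Ccl8 lies at 9.42 with the antibody and 5.28 with IgG, and the dashed line at 4.92 is the 95th percentile of olfactory and vomeronasal receptor genes.

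Interferon-stimulated genes rose as a group, on arrays where the median change was 0.93 for macrophage identity genes, −0.29 for plasma cell markers and −0.38 for stromal markers. Of 29 measured, 28 rose and 0 fell (29 and 0 adjusted over the list alone), with a median change of 1.37 (camera adjusted p = 5.2e-27; adjusted p = 0.054 with an estimated correlation). The largest were Gbp5, the GTPase genes Iigp1 (2.55, SE 0.09) and Gbp3 (1.95, SE 0.06), and Ifit1 (1.85, SE 0.05), whose product binds viral RNA. None of the 21 lists that passed at the preset correlation kept its call once the correlation between genes was estimated from the 6 arrays. The smallest adjusted p was then 0.054. For some of them the estimate lay below the preset 0.01, as for classically activated (M1) macrophage genes (−0.026), chemokines (−0.013) and stromal markers (−0.042). A higher correlation between genes was thus not the reason for every lost call. With an estimated correlation, camera also refers its statistic to the 4 residual degrees of freedom of these arrays, which by itself raises p. A call lost in this way is therefore no evidence that the genes of a list are correlated. At the preset value, the 9 other ways of splitting the 6 arrays into 3 and 3 called 7 to 14 lists. Each of those splits keeps part of the difference between antibody and IgG, so that range is no rate of chance calls. Of 25 chemokines, 14 rose and 2 fell (the same counts, 14 and 2, adjusted over the list alone), with a median of 0.48 (adjusted p = 7.5e-07; adjusted p = 0.054 with an estimated correlation). Besides Ccl8 and Ccl12 these included Cxcl10 (2.37, SE 0.07) and Ccl5 (1.98, SE 0.10), both attractants of T cells. Genes of classically activated (M1) macrophages rose in 10 of 22 cases and fell in 0 (10 and 0 adjusted over the list alone), with a median of 0.24 (adjusted p = 8.1e-06; adjusted p = 0.054 with an estimated correlation). Il1b and the costimulatory receptor gene Cd86 (1.93, SE 0.19) were among them, while other members did not pass, among them Nos2 (5.84 ± 0.16 against 5.60 ± 0.07; adjusted p = 0.10), Il6 (2.83 against 2.81) and Il12b (4.20 against 4.32), named after their values were seen. Il6 and Il12b lay below the background guide in both groups, so these values do not show whether they changed. Nos2 passed without antibody replicate 1 (adjusted p = 0.046) and with only genes above the median signal tested (adjusted p = 0.039). NF-kB and TNF response genes rose in 10 of 18 cases and fell in 2 (10 and 2 adjusted over the list alone), with a median of 0.30 (adjusted p = 0.0014; adjusted p = 0.085 with an estimated correlation). Tnfaip2 (1.57, SE 0.07) and Ikbke (1.48, SE 0.13) changed most, followed by Tnip3 and Bcl3. Over members above the background guide in at least 1 group, a limit set after the data were seen, the median was 1.16 for 12 M1 genes and 1.07 for 18 chemokines.

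Macrophage genes of other functions rose too. Of 20 mature macrophage identity genes, 18 rose and 2 fell (18 and 2 adjusted over the list alone), with a median of 0.93 (adjusted p = 5.3e-13; adjusted p = 0.054 with an estimated correlation). Tlr2, a receptor for bacterial lipopeptides, rose by 1.77 (SE 0.06), Cd14, the lipopolysaccharide co-receptor, by 1.74 (SE 0.07), and the transcription factor gene Maf by 1.67 (SE 0.07). On the same arrays, plasma cell markers had a median change of −0.29. Lysosome and phagocytosis genes rose in 25 of 29 cases and fell in 1 (26 and 2 adjusted over the list alone), with a median of 0.46 (adjusted p = 7.4e-14; adjusted p = 0.066 with an estimated correlation). The Fc receptor genes Fcgr4 (1.85, SE 0.04) and Fcgr3 (1.44, SE 0.05) and the apoptotic-cell bridge Gas6 (1.81, SE 0.05) led that list. MHC class II antigen presentation genes rose in 10 of 13 cases, with 0 falling (10 and 0 adjusted over the list alone) and a median of 0.79 (adjusted p = 7.5e-07; adjusted p = 0.055 with an estimated correlation). H2-DMa rose by 1.49 (SE 0.07), H2-Ab1 by 1.34 (SE 0.05) and H2-Aa by 1.29 (SE 0.07). Of 12 complement genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.93 (adjusted p = 1.7e-05; adjusted p = 0.080 with an estimated correlation). Cfp, for properdin, rose by 1.72 (SE 0.05), C1qa by 1.52 (SE 0.04) and the receptor gene C5ar1 by 1.49 (SE 0.05). Alternatively activated (M2) macrophage genes rose in 13 of 27 cases and fell in 3 (13 and 3 adjusted over the list alone), with a median of 0.17 (adjusted p = 0.00038; adjusted p = 0.080 with an estimated correlation). These were led by Il4ra (1.60, SE 0.06), the receptor chain for IL-4, Cd200r1 (1.56, SE 0.08) and the mannose receptor gene Mrc1 (1.21, SE 0.08). The 3 M2 genes that fell were Fn1 (−0.70, SE 0.06), Il10 (−0.58, SE 0.06) and Irf4 (−0.41, SE 0.06), named after their values were seen. Arg1 stood at 6.03 ± 0.10 against 5.98 ± 0.12 (adjusted p = 0.77) and Cd163 at 4.61 against 4.59 (adjusted p = 0.92), both picked out after their values were seen, and Cd163 lay below the background guide in both groups. Over the 17 M2 genes above that guide the median was 0.56.

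The 4 lists that follow rose on arrays where the median change was 0.93 for macrophage identity genes, −0.29 for plasma cell markers and −0.38 for stromal markers. Inflammatory monocyte genes rose in 7 of 14 cases and fell in 1 (7 and 1 adjusted over the list alone), with a median of 0.35 (adjusted p = 0.00011; adjusted p = 0.055 with an estimated correlation). Ifitm6 (2.58, SE 0.13; below the background guide with IgG), F13a1 (2.53, SE 0.05) and Ms4a4c (2.04, SE 0.09) rose most. Osteoclast genes rose in 7 of 15 cases and fell in 0 (7 and 0 adjusted over the list alone), with a median of 0.08 (adjusted p = 0.0066; adjusted p = 0.19 with an estimated correlation). That median was 0.16 without antibody replicate 1 or IgG replicate 2, and 0.13 without antibody replicate 3, without IgG replicate 3 or with cyclic loess. Those that moved most were Clcn7 (0.99, SE 0.07) and Tcirg1 (0.83, SE 0.05), which acidify lysosomes in many cells as well as the bone-resorbing space, and Tnfrsf11a (0.76, SE 0.08), the receptor for RANKL. Among 10 CSF1R ligands and growth factor receptors, 5 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.47 (adjusted p = 0.0014; adjusted p = 0.066 with an estimated correlation). Besides Csf1r, Csf3r, the receptor for G-CSF, rose by 1.29 (SE 0.05) and Csf2rb2, a beta chain of the IL-3 receptor, by 0.98 (SE 0.07). Macrophage secreted factors known to support myeloma rose in 9 of 18 cases and fell in 3 (9 and 3 adjusted over the list alone), with a median of 0.20 (adjusted p = 0.0054; adjusted p = 0.14 with an estimated correlation). The list's call was also lost in a rank test (adjusted p = 0.070). Il1b led it, with Il18 (1.59, SE 0.08) and Hgf (0.98, SE 0.05). The 3 secreted factors that fell were Il10 (−0.58, SE 0.06), Mmp2 (−0.55, SE 0.11) and Cxcl12 (−0.33, SE 0.08), named after their values were seen. Over members above the background guide, the medians of these 4 lists were 0.67 (10 monocyte genes), 0.23 (11 osteoclast genes), 0.82 (7 ligands and receptors) and 0.38 (15 secreted factors).

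Cell cycle genes fell. Of 38 measured, 0 rose and 37 fell (0 and 37 adjusted over the list alone), with a median of −0.49 (adjusted p = 1.3e-18; adjusted p = 0.055 with an estimated correlation). Tk1, for thymidine kinase, fell by 0.72 (SE 0.05), the centromere protein gene Cenpf by 0.67 (SE 0.05), Tyms, for thymidylate synthase, by 0.65 (SE 0.08) and the mitotic kinase gene Bub1 by 0.64 (SE 0.07). Plasma cell markers fell on the same arrays. Of 22 myeloma and plasma cell markers, 1 rose and 13 fell (1 and 14 adjusted over the list alone), with a median of −0.29 (adjusted p = 5.6e-05; adjusted p = 0.080 with an estimated correlation). Eaf2 fell by 0.68 (SE 0.04) and the B lineage coactivator gene Pou2af1 by 0.63 (SE 0.05), while Slamf7, also made by activated macrophages, rose by 0.55 (SE 0.05). Immunoglobulin probe sets gave signal far above the background guide on all 6 arrays, which were made after the washes. Ighm, the heavy chain gene of IgM, lay at 12.74 ± 0.15 with the antibody and 12.88 ± 0.03 with IgG and did not pass the test (adjusted p = 0.31). Igkj1, a kappa light chain segment, lay at 12.60 ± 0.19 and 12.75 ± 0.08, a change of −0.14 (adjusted p = 0.39). Without antibody replicate 3 both passed, Ighm with a change of −0.22 in place of −0.13 (adjusted p = 0.036) and Igkj1 with −0.25 (adjusted p = 0.038). Ighm also passed with the mean of its probe sets (−0.21; adjusted p = 0.041). Jchain, the joining chain of secreted antibodies, fell by 0.42 (SE 0.05) from 10.09. Ighm, Igkj1 and Jchain were members of the list but picked out here after their values were seen.

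Genes of the unfolded protein response, which is active in plasma cells, fell in 14 of 23 cases and rose in 1 (16 and 1 adjusted over the list alone), with a median of −0.24 (adjusted p = 4.1e-05; adjusted p = 0.082 with an estimated correlation). Chac1 fell by 0.76 (SE 0.05) and Trib3 by 0.63 (SE 0.06), while Atf3, a stress-induced transcription factor gene, rose by 0.77 (SE 0.05). Cytosolic ribosomal protein genes fell in 16 of 24 cases and rose in 0 (19 and 0 adjusted over the list alone), with a median of −0.28 (adjusted p = 2.7e-06; adjusted p = 0.055 with an estimated correlation). Rpl5 fell by 0.55 (SE 0.10) and Rps14 by 0.50 (SE 0.07). With cyclic loess scaling, 8 ribosomal protein genes fell, with a median of −0.16 (adjusted p = 0.00011), and 10 unfolded protein response genes fell, with a median of −0.15 (adjusted p = 0.0020). Nuclear genes of oxidative phosphorylation fell in 10 of 28 cases and rose in 0 (10 and 0 adjusted over the list alone), with a median of −0.16 (adjusted p = 0.0010; adjusted p = 0.12 with an estimated correlation). With cyclic loess scaling this list did not pass (adjusted p = 0.094), as 4 genes fell and 1 rose, with a median of −0.07. The plasma cell marker median of −0.29 stood beside all 3 of these lists. Beside the next 2 lists stood the macrophage identity median of 0.93. Cholesterol synthesis genes rose in 12 of 19 cases and fell in 0 (15 and 0 adjusted over the list alone), with a median of 0.32 (adjusted p = 1.3e-08; adjusted p = 0.054 with an estimated correlation). Stard4, a sterol carrier gene, rose by 1.25 (SE 0.06) and Hmgcs1, for an early enzyme of the pathway, by 0.97 (SE 0.05). LXR and lipid handling genes rose in 9 of 20 cases and fell in 1 (11 and 1 adjusted over the list alone), with a median of 0.37 (adjusted p = 5.2e-06; adjusted p = 0.056 with an estimated correlation). Abca1, the cholesterol exporter gene, rose by 1.17 (SE 0.05) and the lipid droplet gene Plin2 by 0.89 (SE 0.04).

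Several lists held genes that moved both ways and did not pass as lists. Of 24 CSF1R signalling target genes (immediate early genes and MAPK feedback genes), 7 rose and 9 fell (7 and 9 adjusted over the list alone; list adjusted p = 0.90). Their median was −0.08 and their mean 0.08, so the signs differ. With cyclic loess 7 rose and 6 fell, with a median of −0.0042. The members that moved most were Ier3 (1.67, SE 0.14), Jun (1.11, SE 0.06), Egr1 (1.02, SE 0.08) and Fos (0.71, SE 0.07), all of which rose. Myc, picked out after its value was seen, fell by 0.52 (SE 0.06). The list's own members of the Dusp, Spry, Spred and Etv families, grouped after their values were seen, held no rise past the test. Among them Spred2 fell by 0.61 (SE 0.09), Spry4 by 0.49 (SE 0.06), Etv5 by 0.48 (SE 0.08) and Dusp6 by 0.29 (SE 0.06), while Dusp4, Spry1, Spry2 and Spred1 did not pass. Apoptosis and p53 genes rose in 6 of 23 cases and fell in 4 (6 and 5 adjusted over the list alone; list adjusted p = 0.80). Their median was −0.05 and their mean 0.06, and with cyclic loess the median was 0.05. Bcl2l11, for the pro-apoptotic protein Bim, rose by 1.01 (SE 0.07) and the death receptor gene Fas by 0.85 (SE 0.08). Matrix and matrix-degrading genes rose in 11 of 23 cases and fell in 8 (11 and 8 adjusted over the list alone; list adjusted p = 0.11). Their median was −0.17 and their mean 0.31, and over the 22 above the background guide the median was 0.07. With fry, another test of lists, they passed (adjusted p = 7.0e-05), but with an estimated correlation they did not (adjusted p = 0.27). The metalloproteinase genes Mmp27 (1.73, SE 0.07) and Mmp19 (1.71, SE 0.11) rose most. Glycolysis and hypoxia genes rose in 6 of 22 cases and fell in 2 (6 and 2 adjusted over the list alone), with a median of 0.03 and a list adjusted p = 0.053. The list passed with cyclic loess (median 0.13; adjusted p = 0.00082), with arrays centred on their medians (0.0496), with fry (0.0025), without antibody replicate 1 (0.013) and without antibody replicate 2 (0.042). It did not pass with an estimated correlation (adjusted p = 0.50). Ndrg1 (1.71, SE 0.04) and Egln3 (1.26, SE 0.17), both hypoxia-inducible, rose most. NRF2 and metallothionein genes rose in 3 of 15 cases and fell in 7 (3 and 9 adjusted over the list alone; list adjusted p = 0.17), with a median of −0.15 that was −0.05 with cyclic loess. They passed with fry (adjusted p = 0.046) but not with an estimated correlation (adjusted p = 0.45). The iron exporter gene Slc40a1 rose by 1.57 (SE 0.06) and the cystine transporter gene Slc7a11 fell by 0.75 (SE 0.06).

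Markers of other cell types differed from list to list. Fibroblast and stromal cell markers fell in 8 of 15 cases and rose in 1 (10 and 1 adjusted over the list alone), with a median of −0.38 (adjusted p = 0.0036; adjusted p = 0.075 with an estimated correlation). Besides Acta2 and Postn, Tagln fell by 0.81 (SE 0.11) and Sparc by 0.49 (SE 0.08). B cell markers rose in 1 of 12 cases and fell in 2 (1 and 2 adjusted over the list alone; list adjusted p = 0.75), T and NK cell markers rose in 2 of 15 and fell in 0 (2 and 0 adjusted over the list alone; list adjusted p = 0.27). The 2 were Cd4 (2.00, SE 0.10) and Il7r (0.82, SE 0.06). Neutrophil markers rose in 3 of 17 cases and fell in 0 (2 and 0 adjusted over the list alone; list adjusted p = 0.11), namely Csf3r, Mmp8 (1.23, SE 0.07) and Stfa2 (0.26, SE 0.07; below the background guide). Stfa2 lost its call without antibody replicate 1 or 2 or without any of the 3 IgG replicates (adjusted p between 0.085 and 0.11). Dendritic cell markers rose in 4 of 15 cases and fell in 2 (4 and 2 adjusted over the list alone; list adjusted p = 0.23), with a median of −0.01, a mean of 0.23 and a median of 0.12 over the 10 above the background guide. Kmo (1.84, SE 0.07) and the myeloid transcription factor gene Irf8 (1.73, SE 0.05) rose and Itgax, for the integrin CD11c, fell by 0.55 (SE 0.07). None of 11 mast cell and basophil markers passed (0 and 0 adjusted over the list alone; list adjusted p = 0.99), and all 11 lay below the background guide, with Cpa3 at 2.84 against 2.98 and Ms4a2 at 3.62 against 3.74. Erythroid and megakaryocyte markers rose in 2 of 7 cases, the platelet chemokine genes Ppbp (1.41, SE 0.12) and Pf4 (1.23, SE 0.08), and fell in 1, Itga2b (2 and 1 adjusted over the list alone; list adjusted p = 0.17). The T and NK cell (fry adjusted p = 0.024), neutrophil (7.5e-05), dendritic cell (0.00011) and erythroid and megakaryocyte lists (0.00099) passed with fry. No list passed with an estimated correlation.

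**Figure D2:**
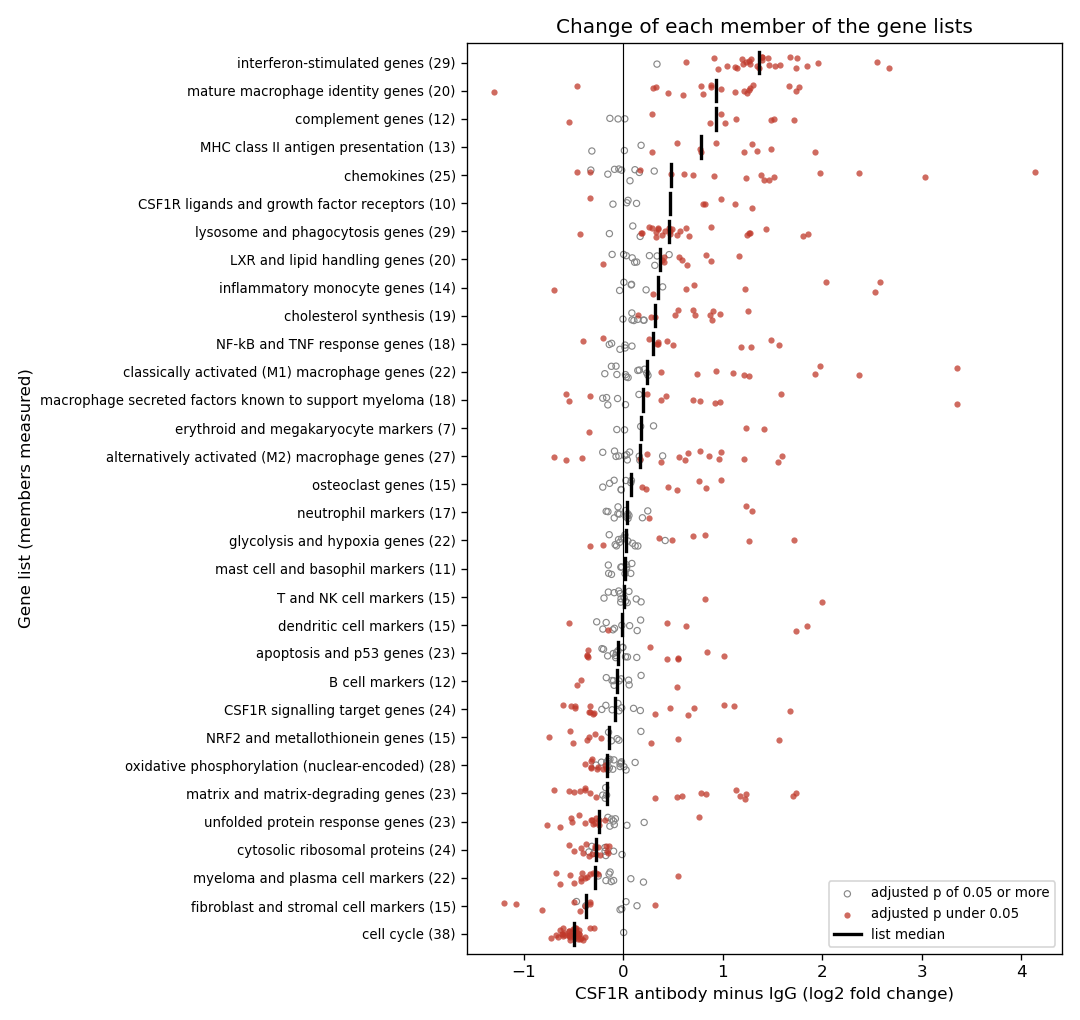
Change of each measured member of the 32 gene lists (CSF1R antibody minus IgG, log2 fold change), with red points for genes with adjusted p under 0.05, open points for the rest and a black bar at the list median. The medians run from −0.49 for cell cycle genes to 1.37 for interferon-stimulated genes.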

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

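Signal was found in probe sets that the comparison of genes did not use. Of 16010 probe sets with no gene in the annotation table, 1329 (8.30%) passed limma's test between CSF1R antibody and IgG when all 41345 probe sets were tested, 417 of them higher and 912 lower with the antibody. Among probe sets with 1 gene symbol, 23.0% passed in the same fit. What these 1329 probe sets measure was not analysed here.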

How the results depend on the processing

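The filter at the receptor level was chosen after the data were seen; the other alternatives were set beforehand. Counts of genes moved by over 1.5 times under 3 settings. At an adjusted p under 0.01, 2232 genes were lower; with a change of at least 2-fold, 641 were higher and 14 lower; with Welch's statistic, which does not share the spread between genes, 1840 were higher and 1845 lower. The first 2 follow from the stricter rule. Without each array in turn, 2439 to 2620 genes were higher and 2839 to 3425 lower. With cyclic loess, 3334 were higher and 2444 lower, 57.7% of the called genes being higher, and the cause was not tested. No scaling moved the median of all genes by more than 0.1. Of 2649 comparisons of 157 genes with their main values, 2608 kept direction and side of the threshold, 36 lost the call, 5 gained it and 0 reversed. The changes were in 10 genes, Actb, Ccnd1, Csf1, Ighm, Igkj1, Ndufa2, Ndufv1, Nos2, Rpl7 and Stfa2, of which Actb, Ccnd1, Ighm, Igkj1 and Nos2 were picked out after their values were seen. Actb, a gene often taken as a control, was higher by 0.16 and lost its call under 9 settings, among them each of 5 left-out arrays. Rpl7, which fell by 0.43, lost the call under 6 settings, among them without each antibody array or IgG replicate 1. Ndufv1, which fell by 0.32, lost it under 7, among them without each antibody array or IgG replicate 1 or 3. Of 441 comparisons of lists, 406 kept theirs, 23 lost and 12 gained a call, and 0 reversed. With an estimated correlation, 0 lists passed, and with fry, which asks only whether a list's genes move one way, 28 did. At most 9 of the 157 genes were left untested by a filter on dim genes, which also left 27 (median filter) or 30 (receptor level) lists to test. Arrays give no depth, and genes near the receptor level of 4.92 have fold changes that background can understate.

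The groups share replicate numbers, but nothing in the labels says what a number marks. Deviations from the group means correlated across genes at 0.03, −0.05 and 0.00 between arrays of the same number, and not every array correlated best with its own number, so the numbers were not taken to pair the arrays. With the replicate number as a block, 2569 genes were higher and 2980 lower, and 22 lists passed, the added one being glycolysis and hypoxia genes (adjusted p = 0.049).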

Other observations

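Toll-like receptor genes, the sensors of microbial and nucleic acid ligands, rose together with the antibody, on arrays where the median change was 0.93 for macrophage identity genes, −0.29 for plasma cell markers and −0.38 for stromal markers. Of 12 measured, 11 rose and 0 fell, with a median change of 1.30 (camera adjusted p = 2.4e-08 over 590 families of symbols with at least 5 members; adjusted p = 0.59 with an estimated correlation). Tlr9 rose by 1.90 (SE 0.10), Tlr7 by 1.81 (SE 0.09), Tlr2 by 1.77 (SE 0.06) and Tlr1 by 1.68 (SE 0.07). Guanylate-binding protein genes rose in 9 of 10 cases, with a median of 1.13 (adjusted p = 1.9e-05; adjusted p = 0.59 with an estimated correlation), Gbp7 by 2.44 (SE 0.06). Schlafen genes rose in 7 of 8 cases with a median of 1.00 (adjusted p = 5.3e-05; adjusted p = 0.59 with an estimated correlation), Slfn5 by 1.49 (SE 0.04) and Slfn2 by 1.29 (SE 0.05). Members of the guanylate-binding and schlafen families are alike in sequence, so probes can pick up more than 1 of them.

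Falls were found in genes of nuclear pores, ribosome assembly and mitochondrial ribosomes, on arrays where the median change was −0.29 for plasma cell markers and −0.49 for cell cycle genes. Nucleoporin genes fell in 14 of 18 cases with a median of −0.34, Nup107 by 0.62 (SE 0.05). Genes of the mitochondrial ribosome's large subunit fell in 22 of 43 cases (median −0.25) and of its small subunit in 20 of 28 (median −0.26), each with adjusted p = 2.6e-05, as for nucleoporins, and adjusted p = 0.59 with an estimated correlation. Nop genes of ribosome assembly fell in 7 of 8 cases (median −0.39; adjusted p = 0.0021; adjusted p = 0.61 with an estimated correlation), Nop16 by 0.54 (SE 0.05). With cyclic loess, fewer fell, 11 nucleoporin, 13 and 10 mitochondrial and 5 Nop genes, and 1 mitochondrial large subunit gene rose. The medians were then −0.25 for nucleoporins, −0.14 and −0.17 for the large and small mitochondrial subunits and −0.28 for Nop genes. The families and genes of these paragraphs were chosen after the values of all 590 were seen, 67 of which passed.

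The tests of explanations that follow were chosen after the results were seen, apart from the splits of the arrays. Macrophage identity genes were higher, while 13 of 22 plasma cell markers fell. The list's brightest probe sets did not pass the test, Ighm at 12.74 against 12.88 with IgG (adjusted p = 0.31) and Igkj1 at 12.60 against 12.75 (adjusted p = 0.39). Both lay at the 99.9th percentile of mean level, near the upper end of the arrays, so the missing calls do not show that myeloma RNA stayed level. Another list also held 6 of the 22 plasma cell markers, 5 of the 15 stromal markers and 6 of the 20 identity genes, several plasma cell markers, such as Slamf7 and Irf4, are also expressed by macrophages, and the 4 washes were meant to remove myeloma cells. A loss of residual myeloma cells as the only change in make-up would, by itself, raise stromal markers too. The stromal median over 12 genes above the receptor level lay below that of 20 identity genes (difference −1.34, bootstrap 95% interval −1.73 to −1.07, permutation p = 0.0028). That argues against such a loss only if the stromal markers track a share of cells. Lower expression of these genes within cells would give the same difference, so the test cannot decide. A larger share of macrophage RNA in the mixture would give like falls of stromal and plasma cell markers. Their medians were −0.41 and −0.33 (difference −0.0745, interval −0.352 to 0.0559, permutation p = 0.27), though a p that misses the threshold does not show that they fell alike. A share alone would also move the identity genes by a like amount, which a test of medians does not see. Their changes ran from −1.29 for Vsig4 to 1.77 for Tlr2. Cd68 and Lyz2, picked out after their values were seen, rose by 0.33 and 0.78. Vsig4 lay near the background guide and Cd68 and Lyz2 were among the brightest genes, so this spread leaves that share undecided. A response of the macrophages themselves to the antibody stays open.

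Interferon-stimulated genes may have risen for more than a larger macrophage share. Their median exceeded that of identity genes by 0.438 (interval 0.0598 to 0.705, one-sided permutation p = 0.00022). Over members with an IgG level of 8 to 12 the excess was 0.250 (interval 0.0263 to 0.592, one-sided permutation p = 0.0028). That argues against this share as the whole cause only if genes are independent and identity genes mark the share well. The correlation estimated within the interferon list was 0.21. Identity genes ran from −1.29 to 1.77, a range that takes in the interferon median of 1.37. An intensity-dependent difference between arrays as the whole cause is argued against by cyclic loess, which removes such trends and moved the balance of higher and lower genes, but left the list's median at 1.49 with 28 of 29 genes higher (camera adjusted p = 9.0e-26 at the preset correlation). Without that scaling, the list's call was lost with an estimated correlation (camera adjusted p = 0.054). A response to the antibody, or to a contaminant of it, was not tested.

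Cell cycle genes fell by more than plasma cell markers in the median, by −0.162 (interval −0.281 to −0.0664; one-sided permutation p = 8e-05). Over members with an IgG level of 8 to 12 the difference was −0.0828 and its interval, −0.198 to 0.00901, took in 0 although the one-sided permutation p was 0.0075. Whether a smaller share of dividing myeloma cells could be the whole cause therefore cannot be told apart from a slower cycle, and the rule that both intervals exclude 0 was set after the values were seen.

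A hypothesis that M1 genes rose more than M2 genes was tested and left open. Their medians differed by 0.0731 (interval −0.386 to 0.857; two-sided permutation p = 0.64), which is too wide to exclude a difference of either sign. Over the 12 M1 and 17 M2 genes above the receptor level the difference was 0.597 (interval −0.0341 to 1.55; two-sided permutation p = 0.079).

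Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave as many calls, with 2766 higher, 3548 lower and 21 lists, against at most 0, 0 and 14 for the others. With 10 splits no share under 0.05 can be had. Each other split mixes antibody and IgG arrays, so the difference between them adds to the spread within its groups. Few gene calls there were thus set by the design and are no measure of chance.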
